A study of Mus musculus with 8 samples.

How the data were processed

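Bone marrow of C57BL/6 mice aged 6 to 8 weeks was, per the labels, flushed from femurs and tibias and cultured with M-CSF, and the macrophages were then given M-CSF at 30 ng/ml and RANKL at 50 ng/ml for 0, 1, 2 or 3 days. Each of the 4 days had 2 arrays, replicates 1 and 2, on the MouseRef-8 v2.0 Expression BeadChip, a single-colour bead array with biotin-labelled cRNA. The deposited signal is, per the file headers, 1 intensity per probe and array, on a linear scale, with no background subtracted and no normalization between arrays as read from its values. Beside each signal the authors deposited a detection p-value, which per the file headers belongs to that signal and whose equal steps imply 798 negative-control values. Control probes were not used here.

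The authors' processed intensity values were on a linear scale as well. Set against the signal of the same array, each was the signal minus a constant and a whole number per probe (whole steps within 0.01 for 94.2% to 97.6% of probes per array), with a median difference of 76.0 to 86.3. Their array medians differed, so they had not been quantile normalized, and what was subtracted is not given in the sources used here. They had no value for 56 probes and served only as an alternative. The scanner software is not given in the sources used here.

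The signals were processed with the neqc function of limma 3.58.1 in R 4.3.3: normexp background correction with the mean and variance of the negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2 transformation. Of 25697 probes, 23978 carried a gene symbol and 1719 did not. By Entrez number 23962 probes matched the RefSeq table (assembly GRCm38.p6), which changed 0 symbols. Probes with a detection p under 0.05 on at least 2 of 8 arrays were kept (12683, of which 11946 had a symbol), and the probe with the highest mean stood for its gene, which left 8663 genes. Of 2347 genes with several detected probes, 25 had probes called in opposite directions from day 0 to day 3. Per array 43.9% to 44.2% of probes were detected and the median signal lay between 165 and 181. For a difference between days the median standard error was 0.12.

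A linear model with 4 day groups was fitted to all 8 arrays with lmFit and eBayes (4 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg per comparison, with 0.05 as the threshold. The comparisons were days 1, 2 and 3 with day 0, day 2 with day 1 and day 3 with day 2, and a moderated F test covered the 4 days together. The comparisons with day 0 share its 2 arrays. The comparison of day 3 with day 1 was used only for genes and lists that took opposite directions at these days. No correction was made over comparisons.

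The 31 gene lists were fixed before the data were examined, as were the tests, the filter and the alternatives, except those named below. The lists covered osteoclast function, V-ATPase subunits, lysosomal proteins, RANK signalling and osteoclast transcription factors, repressors of osteoclast differentiation, NF-kB negative feedback, interferon-stimulated genes, MHC class II presentation, macrophage identity, complement, chemokines and cytokines, oxidative phosphorylation, the tricarboxylic acid cycle, mitochondrial biogenesis, glycolysis, serine and amino acid metabolism, cholesterol biosynthesis, iron handling, S phase, mitosis, ribosome biogenesis and MYC targets, actin ring and podosome, metalloproteinases and inhibitors, histone methyltransferases and demethylases, and markers of 7 kinds of other cells (osteoblast and stromal, neutrophil and granulocyte precursor, B lineage, T and NK, erythroid and megakaryocyte, mast cell and basophil, dendritic). They were written from general knowledge, and 78 of their members were not found on the array. Some genes stand on more than 1 list, such as Sdhb under oxidative phosphorylation and the tricarboxylic acid cycle. The list results are therefore not independent of each other. The 28 lists with at least 5 tested genes were tested with limma's camera (preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry (statmod 1.5.0). List counts are of members that passed over all genes, with counts adjusted over the list alone beside them.

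Genes were named by a rule set before the data were examined. For comparisons with day 0 it took the 10 largest increases and decreases among called genes whose arrays did not overlap between days and that were detected on at least 1 array of each day. It added the 5 largest lower bounds of the fold in each direction among genes detected on no array of 1 day and both of the other, up to 4 called members per list with the largest change, and all measured members of the osteoclast function list. Consecutive days gave 5 in each direction. The lower bound of a fold sets the undetected day at its lowest detected value.

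The model fit was tested on 1 simulated set of data. Among 50 genes each, changes of log2 0.25, 0.5, 1 and 2 were recovered in 2%, 38%, 64% and 94% of cases. Of the calls 4.46% were false, and 0 genes were called in an unchanged comparison. The simulation added independent noise to normalized gene means, so background correction, normalization, the filter and the probe choice were not tested. It changed far fewer genes than were called in the data, so these rates may not hold there. The alternatives were other background corrections, normalizations, filters, probe choices and model settings, the authors' values, and each array left out in turn. Absence of normalization between arrays and quantile normalization of the authors' values were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probes without a symbol were counted but not named, and Atp6v0d2, Oc90 and other genes under the detection filter were not tested.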

Results

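Gene expression was measured in mouse bone marrow-derived macrophages that were cultured with macrophage colony-stimulating factor (M-CSF) and the osteoclast differentiation factor RANKL for 0, 1, 2 or 3 days. Osteoclasts are the multinucleated cells that resorb bone, and they form from macrophage precursors when RANKL is present. The data comprised 8 single-colour bead arrays, 2 for each day, with day 0 as the state before RANKL. No array came from cells kept on M-CSF alone for 1 to 3 days. Effects of RANKL and of time in culture therefore cannot be told apart. Between 11281 and 11361 of 25697 probes were detected on each array, at a mean signal of 720 to 841, and 8663 named genes were tested. Replicate arrays of the same day correlated at r = 0.994 to 0.996 across genes, while arrays of different days correlated at r = 0.881 to 0.986 (genes are not independent replicates). The labels do not say that the 2 arrays of a day came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, with a median standard error of 0.12 on the log2 scale for a difference between days.

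Most measured genes changed at some time in the 3 days. In limma's moderated F test over the 4 days, 6278 of 8663 genes (72.5%) had a Benjamini-Hochberg adjusted p under 0.05. Of these genes, 1875 had their highest mean at day 0, 1717 at day 1, 775 at day 2 and 1911 at day 3. The leading principal component, with 70.2% of the variance, placed the days in their order from day 0 to day 3, and the next, with 21.0%, ran from day 1 at one end to day 0 at the other. Log2 changes below are given with the standard error of the difference (±, n = 2 arrays per day), and adjusted p-values are those of limma with Benjamini-Hochberg adjustment.

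**Figure D1:**
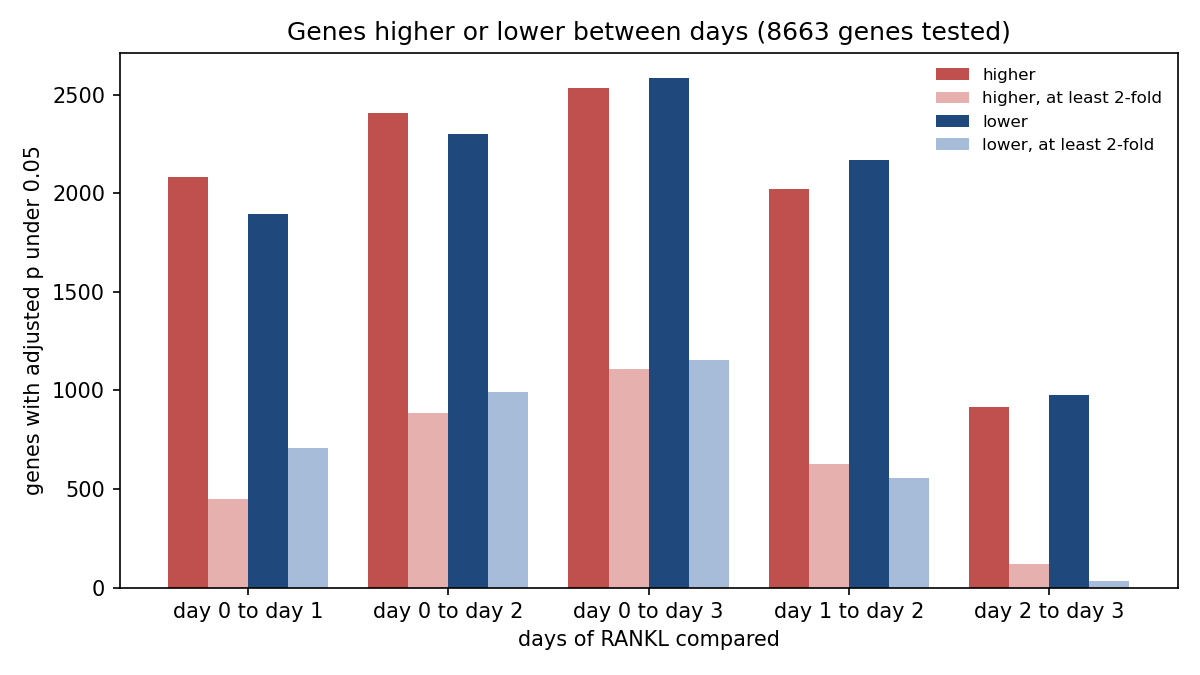
Number of genes (y axis) with a limma adjusted p under 0.05 in each comparison of days (x axis), for all changes and for those of at least 2-fold, among 8663 genes. The counts against day 0 grew from 2083 higher and 1897 lower at day 1 to 2533 higher and 2583 lower at day 3, and the step from day 2 to day 3 held 917 and 978.

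The comparison of day 1 with day 0 asked what differs after a day of RANKL and of further culture. Several genes of bone resorption had already risen, and of 28 osteoclast function genes 14 rose and 5 fell. Mmp9, a gelatinase, rose by 7.21 ± 0.09 (148-fold, limma adjusted p = 2.85e-07), and Ctsk, the main collagen-degrading cathepsin of osteoclasts, rose by 5.77 ± 0.09 (54.6-fold). Chemokine, complement and Fc receptor genes of the macrophage fell over the same day: Ccl7 changed by -6.48 ± 0.19, Fcgr1, the high-affinity IgG receptor, by -5.57 ± 0.13 and C1qa by -4.62 ± 0.15. In all, 2083 genes were higher and 1897 lower at day 1, of which 448 and 709 changed at least 2-fold.

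Of 28 measured genes of the osteoclast function list, 14 rose and 5 fell at day 1 (the same counts when adjusted over the list alone), and 9 did not pass. Among those that rose, Clcn7 lost its call in 7 of 8 settings without 1 array, and Myo1d and Tcirg1 in 3 each. Under the other alternatives, the 2-fold threshold aside, Clcn7 lost its call in 6 and Myo1d in 8. Besides Mmp9 and Ctsk, the kinase gene Src rose by 4.93 ± 0.08 and the membrane-type metalloproteinase gene Mmp14 by 4.66 ± 0.19. The other detected probe of Src gave -0.60 at day 1, 0.64 at day 2 and 0.31 at day 3, none of which passed. Acp5, which codes for tartrate-resistant acid phosphatase, rose by 2.36 ± 0.15 and was detected on 1 of the 2 arrays at day 0. Car2, the carbonic anhydrase that supplies protons for resorption, and Dcstamp, needed for cell fusion, were not well above background at day 0 and were at least 5.81-fold and 4.82-fold higher at day 1. Nfatc1, the central transcription factor of osteoclast differentiation, rose by 1.00 ± 0.13. All 4 detected probes of Nfatc1 were called higher, at 0.86 to 2.36 at day 1, 1.84 to 3.52 at day 2 and 1.91 to 3.44 at day 3. Oscar, an immunoglobulin-like receptor of osteoclasts, gave 0.56 ± 0.25 (limma adjusted p = 0.110), and the RANK gene Tnfrsf11a gave 0.20 ± 0.13 (limma adjusted p = 0.258). Ostm1, Plekhm1, Ckb, Adam8 and Hvcn1 were the members that fell, by 0.73, 1.06, 1.05, 0.56 and 0.97. The other detected probe of Plekhm1 did not pass (-0.70). The list as a whole was higher than other genes by camera (limma, adjusted p = 0.00422), with an adjusted p = 0.0798 with an estimated correlation. Its call was also lost among genes detected on all 8 arrays (limma, adjusted p = 0.101).

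Several regulators rose with these genes. Traf1, an adaptor of tumour necrosis factor receptors, rose by 5.51 ± 0.08, the AP-1 family gene Jdp2 by 4.94 ± 0.11 and the MYC family gene Mycl by 5.30 ± 0.09. The repressor gene Bhlhe40 rose by 4.07 ± 0.19, the caveolin gene Cav1 by 4.05 ± 0.15 and the actin-severing gene Scin by 5.02 ± 0.22. Mycl and Scin were detected on 1 of the 2 arrays at day 0. Vegfc, Mustn1, Fndc7, Tsc22d1 and Sdc1 were not well above background at day 0 and were at least 39.4-fold, 13.6-fold, 13.3-fold, 11.97-fold and 11.5-fold higher at day 1. In the list of RANK signalling and osteoclast transcription factors, 10 of 26 genes rose and 5 fell (11 and 6 adjusted over the list alone), among them Nfkb2 (2.28 ± 0.14) and Fos (2.12 ± 0.14), and Mef2c fell by 2.39 ± 0.17. Of 19 genes on the list named NF-kB negative feedback, 10 rose and 3 fell, and the counts were the same adjusted over the list alone. Beside inhibitors such as Nfkbia and Tnfaip3, this list was written with other targets, such as Icam1, Traf1 and Birc3. It also shares the subunit genes Nfkb1, Nfkb2 and Relb with the RANK signalling list. Its result is therefore not one of feedback inhibitors alone. Cd40, a costimulatory receptor, and Bcl2l1, which codes for the survival factor Bcl-xL, went against the list (-2.79 ± 0.11 and -2.94 ± 0.16). The feedback list passed camera (limma, adjusted p = 0.00662; adjusted p = 0.0825 with an estimated correlation), and the RANK signalling list did not (limma, adjusted p = 0.0922).

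Genes of ribosome assembly rose almost as a block at day 1. Of the 26 measured genes of ribosome biogenesis and MYC targets, 25 rose and none fell (26 adjusted over the list alone), with a median log2 change of 1.05. Myc itself rose by 1.61 ± 0.14, the spermidine synthase gene Srm by 1.42 ± 0.10, Mrto4 by 1.37 ± 0.13 and the nucleolar methyltransferase gene Nop2 by 1.35 ± 0.10. The list had an adjusted p = 1.78e-09 by limma's camera and an adjusted p = 0.0553 with an estimated correlation. Genes of serine, one-carbon and amino acid metabolism rose in 13 of 18 cases and fell in 2 (14 and 2 adjusted over the list alone), including Shmt1 (1.69 ± 0.22), Shmt2 (1.30 ± 0.08) and the amino acid transporter gene Slc7a5 (1.36 ± 0.12). Of 14 genes of mitochondrial biogenesis, 9 rose and none fell, adjusted over the list alone as well, led by the coactivator gene Ppargc1b (2.22 ± 0.10). Of 22 genes of the tricarboxylic acid cycle, 11 rose and 1 fell (12 and 1 adjusted over the list alone), and of 65 genes of oxidative phosphorylation 17 rose and none fell (12 adjusted over the list alone). Of 29 histone methyltransferase and demethylase genes, 13 rose and 1 fell, with the same counts adjusted over the list alone, Dot1l (1.42 ± 0.08) and Prmt1 (1.27 ± 0.17) among them. These 5 lists passed camera (limma, adjusted p between 0.00282 and 0.00628), and each had an adjusted p between 0.0555 and 0.139 with an estimated correlation.

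Macrophage genes fell broadly. In the macrophage identity list, 20 of 25 genes fell and 1 rose, with the same counts adjusted over the list alone. Gas6, a ligand of TAM receptors, fell by 4.96 ± 0.08 (its mean log2 intensity was 11.9 at day 0, 6.91 at day 1 and 11.2 at day 3), the fractalkine receptor gene Cx3cr1 by 3.86 ± 0.27 and the IgG receptor gene Fcgr3 by 3.77 ± 0.12. The complement genes C1qc and C1qb fell by 3.85 ± 0.09 and 3.76 ± 0.14, and 5 of 8 measured complement genes fell, adjusted over the list alone as well. Of 21 chemokine and cytokine genes 14 fell and 1 rose (14 and 2 adjusted over the list alone), including Ccl12 (-5.94 ± 0.25), Ccl4 (-4.92 ± 0.08) and Ccl2 (-4.53 ± 0.16). Of 30 interferon-stimulated genes 24 fell and 1 rose (25 and 2 adjusted over the list alone), such as Ifit2 (-2.95 ± 0.22) and Mx2 (-2.46 ± 0.14). Of 11 genes of MHC class II presentation 9 fell and 1 rose, adjusted over the list alone as well. Repressors of osteoclast differentiation fell in 12 of 14 cases and rose in 1, with the same counts adjusted over the list alone: Id1 fell by 4.29 ± 0.24, Irf8 by 3.30 ± 0.24 and Klf2 by 2.93 ± 0.15. All 6 lists were lower by camera (limma, adjusted p between 1.78e-09 and 0.00258), and with an estimated correlation the adjusted p lay between 0.0555 and 0.108.

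Lipid and lysosomal genes were lower at day 1. Of 17 genes of cholesterol biosynthesis 13 fell and none rose, adjusted over the list alone as well, with Cyp51 at -1.81 ± 0.14 and Fdps at -1.76 ± 0.08. Of 34 lysosomal genes 24 fell and none rose (24 fell and 3 rose adjusted over the list alone), among them the acid lipase gene Lipa (-1.94 ± 0.30) and the cathepsin genes Ctsh (-1.85 ± 0.09) and Ctsc (-1.78 ± 0.08). Both lists had an adjusted p = 2.30e-06 by limma's camera and an adjusted p = 0.0555 with an estimated correlation. The genes with the largest decreases also included the cholesterol 25-hydroxylase gene Ch25h (-6.22 ± 0.17, detected on 1 of 2 arrays at day 1), the neighbouring ribonuclease genes Rnase4 (-6.09 ± 0.22) and Ang (-5.50 ± 0.15) and the iron exporter gene Slc40a1 (-4.93 ± 0.15). Slco2b1, Hpgd, Cdhr3, P2ry13 and Chn2 were not well above background at day 1 and were at least 30.2-fold, 13.05-fold, 12.8-fold, 11.2-fold and 9.84-fold lower than at day 0. S phase genes (3 of 27 higher, 3 lower) and mitosis genes (2 of 22 higher, 3 lower, and 2 each adjusted over the list alone) hardly moved as groups.

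Markers of other cells were followed beside these groups, since a marrow culture can hold them. Of 12 measured neutrophil and granulocyte precursor genes 5 fell at day 1 (6 adjusted over the list alone), among them Mpo (-1.09 ± 0.12, with 1 of 3 probes not passing at -0.35) and Ctsg (-1.20 ± 0.12), and none rose. Of 8 dendritic cell markers 5 fell (6 adjusted over the list alone). These lists passed camera (limma, adjusted p = 0.0191 and 0.00628), with an adjusted p = 0.108 and 0.0848 with an estimated correlation. The neutrophil call was lost without day 0 replicate 2 (limma, adjusted p = 0.0954) and without background correction (limma, adjusted p = 0.0634). Of 5 B lineage markers 1 fell, Cd79b (-1.44 ± 0.15), and of 5 osteoblast and stromal markers 1 rose, adjusted over the list alone as well: Dcn, not well above background at day 0, was at least 4.57-fold higher. Neither list passed camera (limma, adjusted p = 0.687 and 0.815). Of 4 tested T and NK markers Il7r fell by 1.17 ± 0.10 and Klrd1, not well above background at day 1, was at least 1.52-fold lower. Pf4, of 2 tested erythroid and megakaryocyte markers, fell by 2.27 ± 0.21, and Gata2, of 2 tested mast cell and basophil markers, was at least 1.42-fold higher than a day 0 level not well above background.

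Other lists were divided at day 1. V-ATPase subunits were higher in 3 and lower in 3 of 16 cases, with Atp6v0a1 at -3.32 ± 0.11, and glycolysis genes higher in 4 and lower in 4 of 20, adjusted over the list alone as well. Actin ring genes rose in 9 of 29 cases and fell in 6 (10 and 6 adjusted over the list alone), Rhou rising by 2.30 ± 0.23 from a level detected on 1 of 2 arrays at day 0. Iron handling genes rose in 3 of 14 cases and fell in 4, adjusted over the list alone as well, with the heme oxygenase gene Hmox1 at -3.27 ± 0.48. Metalloproteinases and their inhibitors rose in 2 of 12 cases and fell in 5 (3 and 5 adjusted over the list alone), Timp2 at -1.26 ± 0.12. None of these 5 lists passed camera (limma, adjusted p between 0.337 and 0.938).

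After 2 days, the resorption genes stood far above their day 0 level and the energy-producing genes of the mitochondrion had risen together. Mmp9 was higher by 9.19 ± 0.09 (584-fold, limma adjusted p = 2.79e-08), Mmp14 by 7.25 ± 0.19 and Ctsk by 6.82 ± 0.09. Mt3, a metallothionein gene, was not well above background at day 0 and was at least 292-fold higher at day 2. Genes of cell division were lower, as were those of the macrophage and of the interferon response. Compared with day 0, 2410 genes were higher and 2303 lower, with 887 and 990 changed at least 2-fold.

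Of the 28 osteoclast function genes, 23 rose and 3 fell at day 2 (25 and 3 adjusted over the list alone). Oscar rose by 6.28 ± 0.25, Src by 6.42 ± 0.08, Acp5 by 5.08 ± 0.15 (detected on 1 of 2 arrays at day 0) and Nfatc1 by 1.95 ± 0.13. Car2, Dcstamp and Rab38 were at least 48.1-fold, 46.1-fold and 35.7-fold above a day 0 level that was not well above background, and Ocstamp, another gene of cell fusion, was at least 7.99-fold higher. Adam8, Hvcn1 and Cd9 fell. The list had an adjusted p = 3.51e-09 by limma's camera. Among the other genes with the largest increases were Scin (7.36 ± 0.22), the sodium-proton antiporter gene Slc9b2 (6.04 ± 0.09), Slc45a3 (5.56 ± 0.11), Klra17 (5.56 ± 0.22) and Jdp2 (5.42 ± 0.11), of which Scin, Slc45a3 and Klra17 were detected on 1 of 2 arrays at day 0. The thrombin receptor gene F2r, the receptor kinase gene Mst1r, Rufy4 and Apbb1 were at least 150-fold, 92.6-fold, 80.4-fold and 64.7-fold higher, against a day 0 level not well above background.

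Oxidative phosphorylation, tricarboxylic acid cycle and V-ATPase genes rose in most cases. Of 65 nuclear-encoded genes of oxidative phosphorylation 60 rose and none fell (61 adjusted over the list alone), with a median of 0.71 and examples in Ndufb10 (1.71 ± 0.15) and Cyc1 (1.68 ± 0.09). Of 22 genes of the tricarboxylic acid cycle 20 rose and none fell, adjusted over the list alone as well, including Pdhb (2.22 ± 0.12) and Idh3a (1.81 ± 0.09). Of 16 subunits of the V-ATPase, the proton pump of the ruffled border, 13 rose and 1 fell, with the same counts adjusted over the list alone. Atp6v1a rose by 2.11 ± 0.23 and Atp6v1d by 2.03 ± 0.12, while Atp6v0a1 fell (-3.24 ± 0.11). These lists had adjusted p = 4.63e-12, 2.57e-07 and 9.26e-05 by limma's camera. Ppargc1b rose by 4.001 ± 0.10 and Esrra by 1.41 ± 0.09 among 14 mitochondrial biogenesis genes, of which 9 rose and 1 fell, adjusted over the list alone as well (limma camera, adjusted p = 0.00361; adjusted p = 0.0647 with an estimated correlation). Amino acid response genes rose in 12 of 18 cases and fell in 2, adjusted over the list alone as well, led by Chac1 (4.36 ± 0.09) and Asns (2.50 ± 0.12) (limma camera, adjusted p = 0.00204; adjusted p = 0.108 with an estimated correlation). Of 29 actin ring and podosome genes 13 rose and 4 fell, adjusted over the list alone as well, with Rhou (3.87 ± 0.23) and Pxn (2.24 ± 0.09) among those that rose (limma camera, adjusted p = 0.00974; adjusted p = 0.0761 with an estimated correlation).

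Cell cycle genes fell by day 2. Of 22 mitosis genes 19 fell and none rose, and of 27 S phase genes 23 fell and 1 rose, the same counts as adjusted over the list alone. Ndc80 fell by 1.79 ± 0.11, Kif23 by 1.61 ± 0.15, Lig1 by 1.83 ± 0.13 and Mcm3 by 1.63 ± 0.11 (limma camera, adjusted p = 7.02e-08 for mitosis and 2.51e-07 for S phase). Of 19 genes on the NF-kB feedback list 12 rose and 3 fell, adjusted over the list alone as well. Of 26 RANK signalling genes 13 rose and 5 fell (13 and 6 adjusted over the list alone), with Relb, a member of both lists, at 2.36 ± 0.09. The feedback list passed camera and the signalling list did not (limma, adjusted p = 0.00270 and 0.0787; adjusted p = 0.0591 with an estimated correlation for the feedback list). The ribosome biogenesis genes were back near their day 0 level, with 3 higher and 5 lower of 26, adjusted over the list alone as well.

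Macrophage genes were also lower at day 2 than at day 0. In the macrophage identity list 21 of 25 genes fell and none rose (23 adjusted over the list alone), including the sialic acid-binding receptor gene Siglec1 (-6.31 ± 0.18, detected on 1 of 2 arrays at day 2), Fcgr1 (-5.83 ± 0.13) and Cx3cr1 (-5.32 ± 0.27). Of 30 interferon-stimulated genes 28 fell and none rose (28 fell and 1 rose adjusted over the list alone), with Ifit3 at -4.24 ± 0.20 and Irf7 at -3.56 ± 0.17. Ccl7, Ccl2, Ch25h, Id1 and Rgs1 were not well above background at day 2 and were at least 113-fold, 105-fold, 78.1-fold, 46.4-fold and 45.1-fold lower. Ccl12 fell by 6.45 ± 0.25 (detected on 1 of 2 arrays at day 2) and Cxcl14 by 5.43 ± 0.19, and 17 of 21 chemokine and cytokine genes fell while 3 rose, adjusted over the list alone as well. C1qa fell by 5.57 ± 0.15, and the complement list (4 of 8 lower, 1 higher, adjusted over the list alone as well) barely passed camera (limma, adjusted p = 0.0478; adjusted p = 0.269 with an estimated correlation) and lost its call without day 0 replicate 2 (limma, adjusted p = 0.0516), day 1 replicate 2 (limma, adjusted p = 0.0507) or day 3 replicate 2 (limma, adjusted p = 0.0502). Repressors of osteoclast differentiation fell in 13 of 14 cases and MHC class II genes in 9 of 11 (13 and 10 adjusted over the list alone). Neutrophil and granulocyte precursor markers fell alongside in 10 of 12 cases, adjusted over the list alone as well, with Mpo at least 4.71-fold lower and S100a8 lower by 1.98 ± 0.11. The interferon list had an adjusted p = 4.70e-12 by limma's camera and an adjusted p = 0.0760 with an estimated correlation, whereas the macrophage, chemokine, repressor, MHC class II and neutrophil lists passed with both (limma, adjusted p between 0.0239 and 0.0463 with the estimated one).

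The remaining lists did not pass camera at day 2 (limma, adjusted p between 0.0787 and 0.963). Lysosomal genes were higher in 13 and lower in 14 of 34 cases, with Arsb, an arylsulfatase gene, at 2.74 ± 0.09. Glycolysis genes were higher in 9 and lower in 5 of 20 cases, metalloproteinases and inhibitors higher in 3 and lower in 7 of 12, iron handling genes higher in 5 and lower in 5 of 14 and dendritic cell markers higher in 3 and lower in 5 of 8, all adjusted over the list alone as well. Cholesterol genes were higher in 4 and lower in 6 of 17 cases (4 and 7 adjusted over the list alone), and histone methyltransferase and demethylase genes higher in 8 and lower in 3 of 29 (6 and 2 adjusted over the list alone), Kdm3a rising by 1.60 ± 0.13. B lineage markers fell in 3 of 5 cases, adjusted over the list alone as well, with Cd79b not well above background at day 2 and at least 4.41-fold lower. Of the osteoblast and stromal markers Dcn alone rose, adjusted over the list alone as well, and was at least 3.90-fold higher. Il7r fell by 3.67 ± 0.10, and Pf4 was lower by 4.48 ± 0.21.

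By day 3 osteoclast function, oxidative phosphorylation and macrophage identity genes still stood apart from day 0, and mitosis, S phase and ribosome assembly genes had fallen further. Mmp9 was higher by 9.38 ± 0.09 (665-fold, limma adjusted p = 2.43e-08), Mmp14 by 7.80 ± 0.19, Oscar by 7.29 ± 0.25 and Acp5 by 5.92 ± 0.15. Mt3 was at least 490-fold higher and Dcstamp at least 74.2-fold higher, neither being well above background at day 0. Of the interferon-stimulated genes, all 30 measured were lower. Against day 0, 2533 genes were higher and 2583 lower, with 1111 and 1157 changed at least 2-fold.

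**Figure D2:**
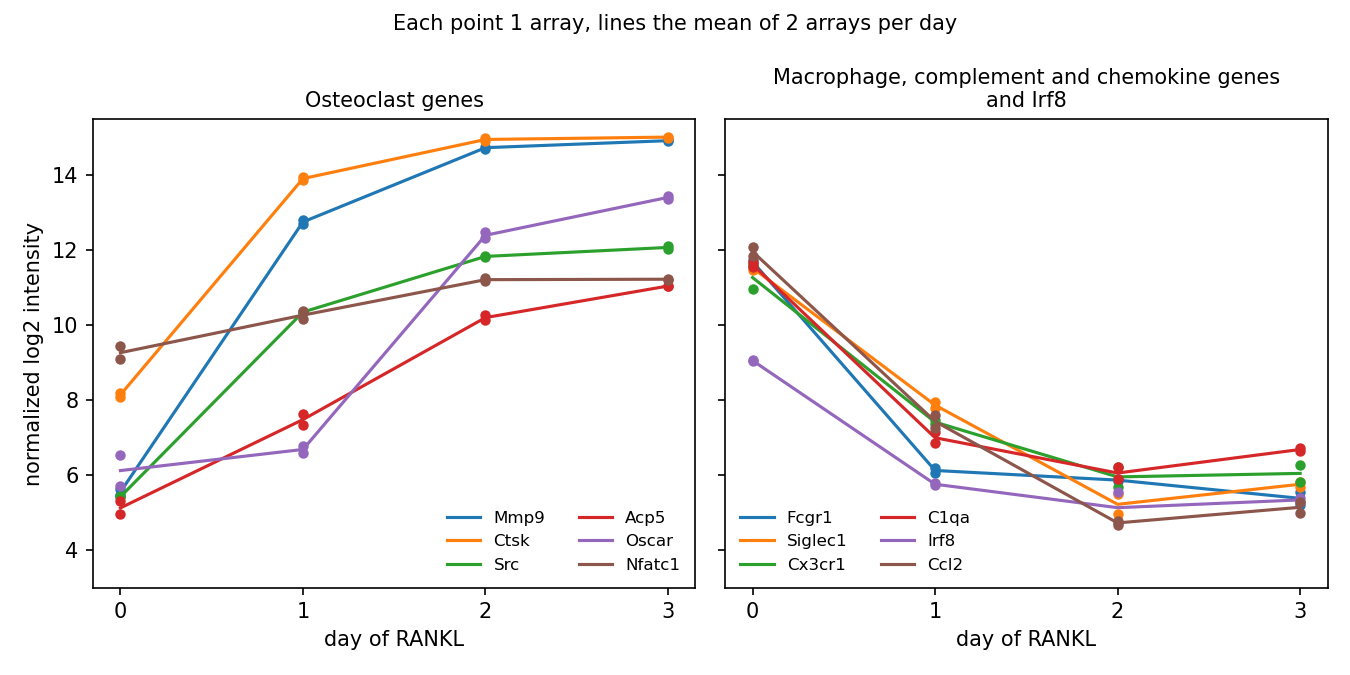
Normalized log2 intensity (y axis) by day of RANKL (x axis) for 6 osteoclast genes and for 6 genes of macrophage identity, complement, chemokines and repression, with each point an array and each line the mean of the 2 arrays of a day. Oscar lay at a mean of 6.69 at day 1 and 12.4 at day 2, and Ctsk already stood at 13.9 at day 1.

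Of the 28 osteoclast function genes 24 rose and 2 fell at day 3, adjusted over the list alone as well. The chloride-proton exchanger gene Clcn7 rose by 2.69 ± 0.10, the V-ATPase subunit gene Tcirg1 by 1.67 ± 0.08, the anion exchanger gene Slc4a2 by 2.19 ± 0.09 and Snx10 by 2.51 ± 0.15. The calcitonin receptor gene Calcr was at least 3.59-fold higher, and Tnfrsf11a rose by 0.60 ± 0.13, a call that was lost with the authors' processed values and without normalization between arrays. Adam8 fell by 2.94 ± 0.10 and Hvcn1 by 0.97 ± 0.09. The list had an adjusted p = 3.62e-09 by limma's camera. Further genes with large increases were Scin (7.15 ± 0.22), Src (6.66 ± 0.08), Klra17 (6.20 ± 0.22), Slc9b2 (6.06 ± 0.09) and Denn2b (5.87 ± 0.12), and Acp5, Scin and Klra17 were detected on 1 of 2 arrays at day 0. F2r, Mst1r, Tmem204 and the sphingosine kinase gene Sphk1 were at least 120-fold, 104-fold, 101-fold and 95.1-fold higher than a day 0 level not well above background. The other detected probe of Sphk1 gave 0.27 and did not pass.

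Oxidative phosphorylation and tricarboxylic acid cycle genes kept their raised level against day 0. At day 3, 58 of 65 oxidative phosphorylation genes rose and none fell (61 adjusted over the list alone), with Atp5a1 at 1.96 ± 0.28 and Sdhb at 1.74 ± 0.12, and 20 of 22 genes of the tricarboxylic acid cycle rose, adjusted over the list alone as well, with Mdh1 at 2.36 ± 0.27 (its other detected probe gave 0.60 and did not pass). V-ATPase subunits rose in 14 of 16 cases, adjusted over the list alone as well. Atp6v1a was up by 2.99 ± 0.23, and Atp6v0a1 was the member that fell (-2.75 ± 0.11). These lists had adjusted p = 4.42e-12, 3.16e-07 and 3.29e-05 by limma's camera. Of 20 glycolysis genes 9 rose and 3 fell, adjusted over the list alone as well: Aldoc rose by 3.26 ± 0.17 and Pdk1, which restrains pyruvate dehydrogenase, by 2.21 ± 0.10, while Hk3 fell by 2.52 ± 0.08. The glycolysis list had an adjusted p = 0.0483 by limma's camera and an adjusted p = 0.130 with an estimated correlation. That call was lost without day 0 replicate 2 (limma, adjusted p = 0.0693) and without day 3 replicate 1 (limma, adjusted p = 0.0640). The actin ring list had 17 of 29 genes higher and 3 lower, and the NF-kB feedback list 12 of 19 higher and 3 lower, both adjusted over the list alone as well (limma camera, adjusted p = 0.00992 and 0.00354; adjusted p = 0.0749 and 0.0589 with an estimated correlation).

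Proliferation and ribosome assembly genes were lower at day 3. Of 22 mitosis genes 21 fell (22 adjusted over the list alone), among them Plk1 (-2.19 ± 0.12) and Cdk1 (-2.16 ± 0.10). Of 27 S phase genes 24 fell and 1 rose, adjusted over the list alone as well, such as Mcm3 (-2.40 ± 0.11), Tk1 (-2.39 ± 0.12) and Cdc45 (-2.23 ± 0.10). Of 26 ribosome biogenesis genes 15 fell and none rose, adjusted over the list alone as well, with Nop56 at -1.04 ± 0.12 and Polr1a at -0.90 ± 0.08. The 3 lists had adjusted p = 3.53e-10, 5.69e-09 and 0.00129 by limma's camera.

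Most macrophage identity genes and all 30 interferon-stimulated genes were lower at day 3 than at day 0. Macrophage identity genes fell in 21 of 25 cases, adjusted over the list alone as well: Fcgr1 by 6.32 ± 0.13 (detected on 1 of 2 arrays at day 3), Siglec1 by 5.78 ± 0.18 and the receptor kinase gene Axl by 5.17 ± 0.12. The interferon-stimulated genes Ifit3, Irf7 and Oasl2 fell by 4.68 ± 0.20, 4.33 ± 0.17 and 3.96 ± 0.13, and the 30 lower genes were 30 adjusted over the list alone as well (limma camera, adjusted p = 3.04e-12; adjusted p = 0.0715 with an estimated correlation). Chemokine and cytokine genes fell in 16 of 21 cases and rose in 2, adjusted over the list alone as well (limma camera, adjusted p = 3.29e-05; adjusted p = 0.0589 with an estimated correlation). Ccl2 fell by 6.83 ± 0.16 (detected on 1 of 2 arrays at day 3) and Ccl4 by 5.69 ± 0.08, and Ccl7, Ch25h, Slco2b1, Dnmt3l and Cyp4f18 were at least 114-fold, 78.5-fold, 30.0-fold, 29.8-fold and 25.8-fold lower, not being well above background at day 3. Rnase4 and Ang fell by 6.12 ± 0.22 and 5.92 ± 0.15. Repressors fell in 12 of 14 cases and MHC class II genes in 9 of 11, adjusted over the list alone as well. Neutrophil and granulocyte precursor markers again moved with these groups, with 10 of 12 lower, adjusted over the list alone as well, Ctsg at least 3.06-fold lower and S100a8 lower by 2.16 ± 0.11. Pf4, the platelet factor 4 gene among the megakaryocyte markers, fell by 4.37 ± 0.21, and Il7r, a lymphoid marker, by 4.08 ± 0.10. Cd5 and Lat, on the T and NK list, were at least 4.03-fold and 3.61-fold higher, against a day 0 level not well above background.

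The lists that did not pass camera at day 3 held strong changes of single genes. Lysosomal genes were higher in 14 and lower in 12 of 34 cases (15 and 13 adjusted over the list alone), with Arsb at 3.49 ± 0.09 and the galactosidase gene Glb1 at 2.21 ± 0.11. Of 14 iron handling genes 5 rose and 5 fell, adjusted over the list alone as well: the transferrin receptor gene Tfrc rose by 2.53 ± 0.10 and the ferritinophagy gene Ncoa4 by 2.77 ± 0.14, while Hmox1 fell by 3.26 ± 0.48. RANK signalling genes rose in 14 of 26 cases and fell in 6 (14 and 7 adjusted over the list alone), with Mef2c at -3.46 ± 0.17. Serine and amino acid response genes rose in 9 of 18 cases and fell in 3, mitochondrial biogenesis genes rose in 7 of 14 and fell in 2, and cholesterol genes rose in 9 of 17 and fell in 2, adjusted over the list alone as well, with Insig1 at 1.40 ± 0.11. Histone methyltransferase and demethylase genes were higher in 6 and lower in 5 of 29 cases, metalloproteinases and inhibitors higher in 4 and lower in 7 of 12, and complement genes higher in 3 and lower in 4 of 8, adjusted over the list alone as well. Dendritic cell markers were higher in 3 and lower in 5 of 8 cases, adjusted over the list alone as well. Among them Cd83 rose by 2.01 ± 0.15 and Bst2, also on the interferon-stimulated list, fell by 2.78 ± 0.24. B lineage markers fell in 2 of 5 cases, and of 5 osteoblast and stromal markers 1 rose, adjusted over the list alone as well. The adjusted p of these lists lay between 0.0573 and 0.821 (limma camera).

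**Figure D3:**
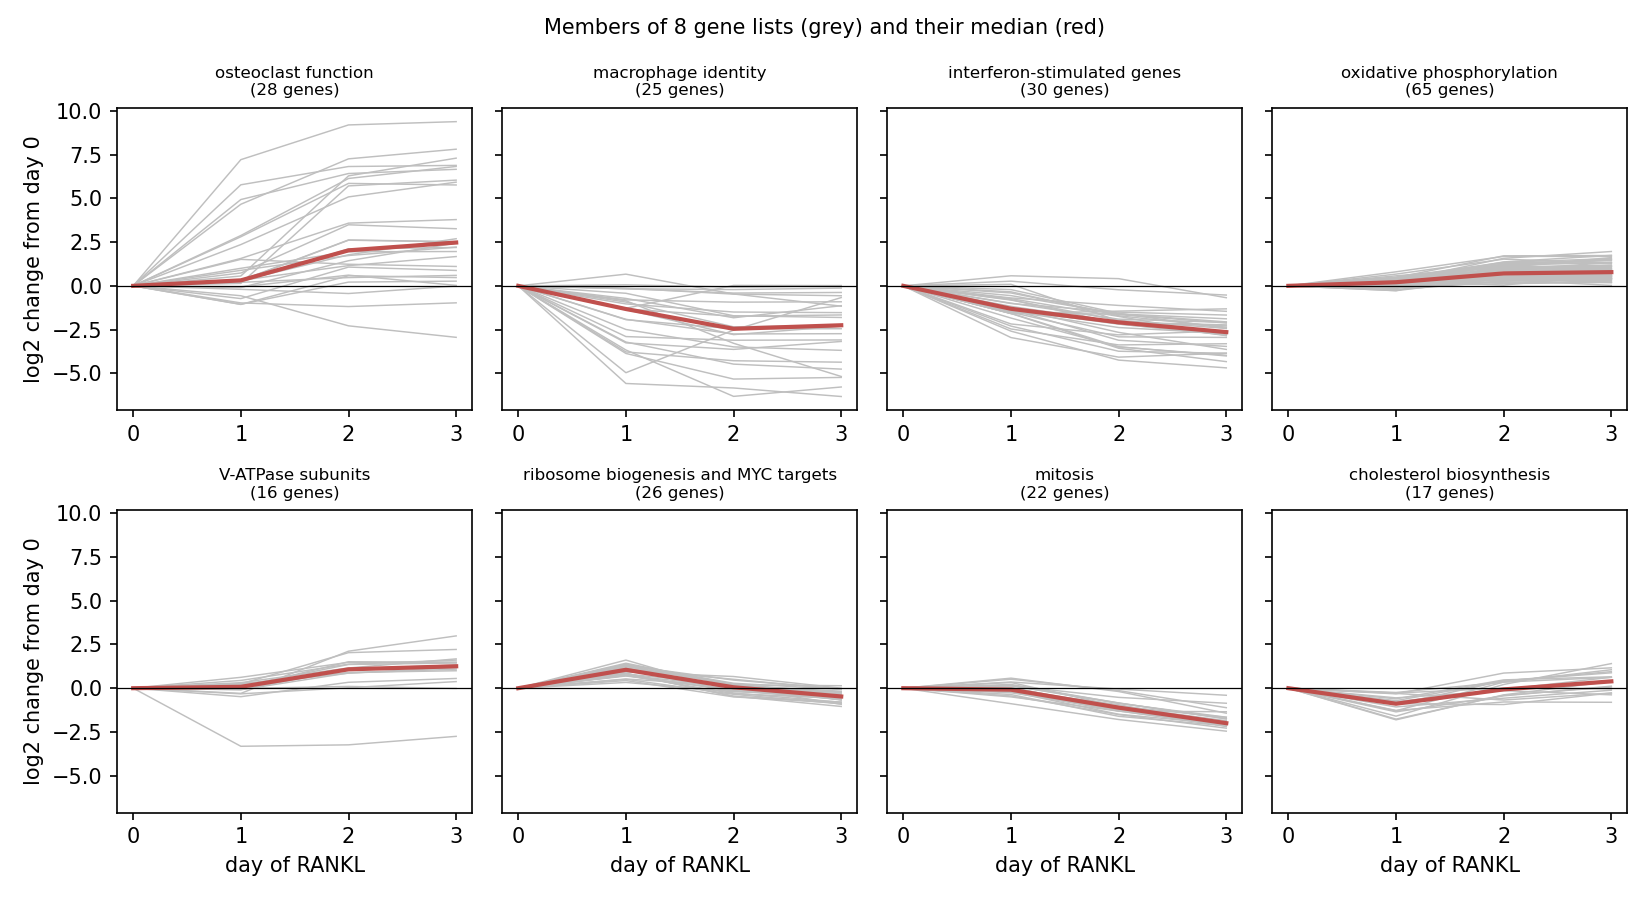
Log2 change from day 0 (y axis) by day of RANKL (x axis) for the members of 8 gene lists (grey lines) and their median (red line). The ribosome biogenesis median lay at 1.05, 0.05 and -0.47 at days 1, 2 and 3, and the mitosis median at -0.09 and -1.11 at days 1 and 2. Without normalization between arrays the ribosome median at day 2 lay at -0.015.

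The step from day 1 to day 2 was tested directly. Mt3 rose by 7.25 ± 0.09 (152-fold, limma adjusted p = 1.73e-07), Oscar by 5.72 ± 0.25, F2r and Klra17 by 5.20 each (± 0.11 and 0.22), and Mst1r by 4.70 ± 0.11. Podoplanin, coded by Pdpn, fell by 3.72 ± 0.17, the protease inhibitor gene Slpi by 3.44 ± 0.14, AA467197 by 3.38 ± 0.12, Dnmt3l fell by 3.24 ± 0.11 (detected on 1 of 2 arrays at day 2) and the cytokine signalling inhibitor gene Socs3 also fell (-2.83 ± 0.20). In all, 2023 genes were higher and 2170 lower at day 2 than at day 1. Osteoclast function genes rose in 23 of 28 cases in this step and fell in 2, adjusted over the list alone as well. Among those that rose were Dcstamp (3.26 ± 0.15), Car2 (3.05 ± 0.11) and Acp5 (2.72 ± 0.15). In this step Cd9 lost its call in 8 settings without 1 array and in 5 other alternatives, and Itgb3 in 6 and 4. Ribosome biogenesis genes fell in 25 of 26 cases and cholesterol biosynthesis genes rose in 14 of 17, both adjusted over the list alone as well (limma camera, adjusted p = 1.03e-09 and 1.65e-05). V-ATPase subunits rose in 14 of 16 cases, adjusted over the list alone as well, and oxidative phosphorylation genes in 52 of 65 (56 adjusted over the list alone). S phase genes fell in 25 of 27 cases (26 adjusted over the list alone) and mitosis genes in 21 of 22 (22 adjusted over the list alone).

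From day 2 to day 3 fewer genes changed, and mostly by less. Corin, a serine protease gene, rose by 3.42 ± 0.16 (10.7-fold, limma adjusted p = 0.000194), Enpp5 by 2.59 ± 0.13, the histone gene H2ac18 by 2.55 ± 0.09, the serotonin receptor gene Htr2b by 2.47 ± 0.12 and the cell cycle inhibitor gene Cdkn1c by 2.44 ± 0.11. Axl fell by 1.90 ± 0.12, Cish by 1.71 ± 0.25, Fbxl13 by 1.70 ± 0.20, Tmem267 by 1.51 ± 0.16 and Adig by 1.36 ± 0.26, Cish and Adig being detected on 1 of 2 arrays at day 3. The counts were 917 higher and 978 lower, of which 122 and 35 changed at least 2-fold. Mitosis genes fell in 20 of 22 cases, S phase genes in 19 of 27 and ribosome biogenesis genes in 16 of 26 (20, 22 and 21 adjusted over the list alone; limma camera, adjusted p = 1.61e-13, 1.79e-09 and 1.96e-08). Lysosomal genes rose in 17 of 34 cases (20 adjusted over the list alone; limma camera, adjusted p = 4.92e-07; adjusted p = 0.0582 with an estimated correlation). Among osteoclast function genes 8 of 28 rose and 1 fell, adjusted over the list alone as well, Acp5 (0.84 ± 0.15) and Calcr (1.00 ± 0.12) among those that rose, while Ctsk gave 0.06 ± 0.09, Mmp9 0.19 ± 0.09, Nfatc1 0.01 ± 0.13 and Car2 -0.09 ± 0.11, none of which passed. The Acp5 call was lost without day 2 replicate 1 or day 3 replicate 2. Without 1 array the Oscar call of this step was lost in 6 settings, and those of Cd9, Dcstamp and Gpr137b in 3 each. The Adig call was lost without day 2 replicate 1 and with only the arrays of the days compared. The day 2 to day 3 counts depend on single arrays: without day 2 replicate 1 they were 284 higher and 239 lower, without day 2 replicate 2 389 and 328, without day 3 replicate 1 511 and 560, and without day 3 replicate 2 350 and 382. They also depend on the scaling, with 404 higher and 1489 lower without normalization between arrays.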

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

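The tests of the ribosome genes against scaling and against proliferation genes were chosen only after the result was seen. The genes in the next paragraph were singled out because they passed in opposite directions at day 1 and day 3 against day 0, with the step from day 1 to day 3 tested itself, and the probes at the end because no gene comparison used them.

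In all, 398 genes were higher at day 1 and lower at day 3 and 300 lower at day 1 and higher at day 3. These counts were not recomputed under the alternatives and may depend on the scaling. Without normalization between arrays the median of all genes lay at 0.110 at day 1 and -0.154 at day 3. A shift of that kind favours the former count over the latter. Among named genes that fell from day 1 to day 3 were Pdpn (log2 change -2.96), Slpi (-2.86), the ribosome and MYC genes Mrto4 (-2.03), Noc4l (-1.999), Srm (-1.97), Nop56 (-1.90), Polr1a (-1.41) and Odc1 (-1.29), the transporter gene Slc7a5 (-1.90), the methyltransferase gene Smyd5 (-1.91), Mcm7 (-2.02), Cdc20 (-2.001) and Bub1b (-1.63). Those that rose were Arsb (4.33), Aldoc (3.96), Cd83 (at least 3.94, as it was detected on no array at day 1), Cdkn1c (3.20), Insig1 (3.001), Glb1 (2.64), Cyp51 (2.20), Timp2 (1.86), Srebf2 (1.66), Ostm1 (1.61), Plekhm1 (1.53), Ckb (1.32) and Atp6v0d1 (1.04). Some of the calls against day 0 behind these depend on single settings. Ckb at day 3 was lost in 4 of 8 settings without 1 array and in 2 alternatives. Without 1 array Atp6v0d1 at day 1 was lost in 2 settings, and Srebf2 at day 3 and Aldoc at day 1 in 1 each. Plekhm1 at day 3 was lost with mean of probes. Cyp51 at day 3 (0.39, limma adjusted p = 0.0478) and Srebf2 at day 1 (-0.71, limma adjusted p = 0.0458) passed narrowly. These 2 calls were not recomputed under the alternatives.

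The ribosome biogenesis list had a median change of -1.45 from day 1 to day 3, after 1.05 at day 1. The list median was at least 0.946 at day 1 in 4 scaling alternatives, no normalization between arrays among them, and at most -0.455 at day 3. In these settings the median of all genes lay only between -0.035 and 0.110 at day 1 and between -0.154 and 0.080 at day 3. Array brightness thus differed too little to give changes of this size, which argues against scaling of the arrays as the cause. The values also argue against a general rise of proliferation genes, since 49 S phase and mitosis genes had a median of 0.072 at day 1. The list lay above them by 0.979, with a bootstrap 95% interval from 0.694 to 1.15 (10000 resamples). Genes were resampled, and these are not independent replicates, so the interval leaves out the spread between arrays. No other explanation was tested.

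Neutrophil granule genes were lower after RANKL. If granulocyte precursors in the day 0 cultures were the source, at least 8 of 10 abundant transcripts would be detected on both day 0 arrays and every one of these would be lower at day 3. Of the 10, 8 were so detected, and 7 of these were lower. Camp did not pass (-0.82, limma adjusted p = 0.0775) and Ngp was not detected at day 0. S100a8 stood at a log2 of 9.48 at day 0, at the 64.9 percentile of genes. A loss of such cells and a fall of these genes in the macrophages cannot be told apart, because no measurement of cell types was made.

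Atp6v0a1 fell while most V-ATPase subunits rose, and 1 other detected probe of the gene was lower as well (-2.75 and -2.10 at day 3). Of 737 detected probes without a gene symbol, 394 (53.5%) were called from day 0 to day 3, 189 higher and 205 lower, and were not analysed further here.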

How the results depend on the processing

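The named genes, the lists against day 0 and the counts of changed genes and lists were recomputed under 19 alternatives and without each of 8 arrays. The counts of genes that took opposite directions at day 1 and day 3 were not. Of 479 named gene calls, 22 were lost in at least 1 alternative other than the 2-fold threshold and 25 without at least 1 array. The naming rule favoured genes with large changes, so these losses do not measure how often other calls would be lost. No named gene call and no list call against day 0 changed direction. The directions of other genes and lists were not analysed here. For the changed results below the cause was not tested, except where fewer arrays, fewer genes or a threshold show it. Without 1 array, 1 array remains in a day and is assumed to vary like the others. No normalization between arrays and quantile normalized authors' values were chosen after seeing the data. The chip as a block was not run, since the files name no chip. The sample numbering sets days 0 and 3 apart from days 1 and 2. Whether these days were also processed apart could not be tested, and such a batch could not be told apart from the day. Low signal over background limits the genes undetected on a day.

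At least 2-fold left 448 higher and 709 lower at day 1, 887 and 990 at day 2, 1111 and 1157 at day 3, 629 and 557 from day 1 to day 2, and 122 and 35 from day 2 to day 3. From day 2 to day 3, 464 were higher and 1699 lower with the authors' processed values, 404 and 1489 with no normalization between arrays, 554 and 488 with only the groups compared, and 630 were lower with no filter on dim probes. Without 1 array they ranged from 284 to 927 higher and from 239 to 952 lower. The share of calls that were higher moved from 48.4% to 21.5% and 21.3% with the authors' values and without normalization in that step, from 49.5% to 38.5% and 38.6% from day 0 to day 3, from 48.2% to 37.5% and 37.3% from day 1 to day 2, and from 52.3% to 62.3% and 61.4% from day 0 to day 1. In that last step cyclic loess gave 1753 higher and 2167 lower. Without normalization the median of all genes lay at 0.110 at day 1, -0.154 at day 3, -0.114 from day 1 to day 2 and -0.147 from day 2 to day 3, and with the authors' values at -0.111 at day 3 and -0.119 from day 2 to day 3.

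Of 18, 17 and 16 list calls at days 1, 2 and 3, camera with an estimated correlation kept 0, 11 and 11, and fry gave 26 at day 2 and 26 at day 3. The complement call at day 2 also ended with cyclic loess (limma, adjusted p = 0.0606), detection p under 0.01 (0.0543), detection on all arrays (0.108), mean of probes (0.0557) and every probe (0.0967), and the glycolysis call at day 3 with mean of probes (0.0725) and array weights (0.0510). With the replicate block the calls were 1989 higher and 1852 lower at day 1, 2336 and 2274 at day 2, 2509 and 2544 at day 3, and 774 and 810 from day 2 to day 3. No deviation shared by arrays of the same replicate number was visible (correlation of deviations from -0.0820 to 0.0677 over 6 pairs of days). That check cannot show whether such arrays came from the same culture or animal.

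Results that had not passed took the other direction as follows, with none passing. With cyclic loess, the ribosome list lay at -0.027 at day 2 and the histone list at -0.0052 at day 3. With scaling to a common median, lysosomal genes lay at 0.0080, iron at 0.0034 and osteoblast markers at 0.0050 at day 2, the last at 0.070 at day 3. With the authors' processed values, mitosis lay at 0.012, actin at 0.069 and B lineage at 0.10 at day 1, ribosome at -0.0049 at day 2 and histone at -0.13 at day 3, with Ctsk at -0.026 and Nfatc1 at -0.13 from day 2 to day 3. With no normalization between arrays these were 0.013, 0.037, 0.0014, -0.015, -0.12, -0.026 and -0.13. B lineage lay at 0.083 with the authors' values quantile normalized, osteoblast markers at 0.042 at day 3 with no filter on dim probes, and lysosomal genes at -0.00029 at day 3 with detection on all arrays. With mean of probes, mitosis lay at 0.0075 at day 1 and lysosomal genes at 0.036 at day 2, and with every probe actin lay at 0.020 at day 1, and lysosomal genes at 0.039 and cholesterol at 0.21 at day 2. Without 1 array the ranges were -0.035 to 0.10 for actin, -0.036 to 0.17 for glycolysis, -0.27 to 0.039 for B lineage and -0.14 to 0.053 for osteoblast markers at day 1. At day 2 they were -0.36 to 0.22 for osteoblast markers, -0.11 to 0.074 for cholesterol, -0.27 to 0.060 for iron and -0.020 to 0.067 for ribosome genes. At day 3 they were -0.045 to 0.12 for histone, -0.0035 to 0.082 for lysosomal genes and -0.17 to 0.18 for osteoblast markers, and -0.024 to 0.047 for Nfatc1 from day 2 to day 3.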

Other observations

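The tests of gene families, of neighbours changed at least 4-fold, and of expression level and overlap among neighbours were chosen only after the result was seen. Of 121 gene families by name stem, 14 passed limma's camera at day 1 with the preset correlation and none with an estimated one (adjusted p = 1.19e-05 and 0.238 for Mrpl). Genes of mitochondrial ribosome proteins rose, 34 of 44 Mrpl and 20 of 27 Mrps genes, with none lower, as did 14 of 18 Polr, 7 of 8 Exosc, 10 of 14 Nup, 13 of 18 Gtf and 14 of 21 Ddx genes and 23 of 38 Eif genes, of which 2 fell. Among families that passed as lower, 23 of 52 Rab genes fell (2 higher), 12 of 25 Snx genes and 13 of 24 Arhgap genes (3 higher), while of 26 Vps genes 2 rose and 3 fell. At day 3, 15 of 21 Cox genes and 8 of 10 Ndufb genes were higher and 7 of 10 Irf genes lower. None of these passed with an estimated correlation.

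Neighbouring genes changed together more often than shuffled ones. From day 0 to day 3, 1577 of 8281 neighbouring pairs were called the same way (gene order of GRCm38.p6, pairs with the same name stem left out). Over 10000 shuffles the mean was 1444 and the central 95% was 1387 to 1502 (permutation test, p = 0.0001, the smallest these shuffles can give). Chromosomal neighbourhood may be the source, but the count is the pattern itself and cannot show its source. Related genes with unlike name stems, such as Trem2 and Treml1 or Igtp and Irgm2, stayed among the pairs. Their share of the excess was not tested. Neighbours of like expression level do not explain the excess, since shuffles within bins of mean expression gave 1401 to 1517 (permutation test, p = 0.0001). Neither do overlapping genes that share transcripts, since 1475 of 7808 pairs remained without 473 overlapping ones (permutation test, p = 0.0001). The excess was small, 1.09 times the shuffled mean. Among 791 genes changed at least 4-fold there were 56 such pairs against a mean of 34.6 (24 to 46, permutation test, p = 0.0003). Rnase4 and Ang, Rsad2 and Cmpk2, and Bdh2 and Slc9b2 were among them. Overlapping pairs were not left out of this count.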
